A study of Homo sapiens with 12 samples.

How the data were processed

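RNA was sequenced from 12 cultures of MCF-7, an estrogen receptor-positive human breast cancer cell line, in 4 groups of 3 replicates lettered A, B and C. The control line carried no vector. Each of the other 3 lines stably expressed a GFP fusion of a SEPT9 isoform (SEPT9_v1, SEPT9_v2 or SEPT9_v3) from the CMV promoter and had been sorted for GFP. Per the labels' protocols, the lines were grown in parallel, each was divided into its 3 replicates, and plates were lysed below full confluence. Libraries were made from fragmented mRNA with random primers, and the labels do not state a protocol that marks the strand. There was 1 line per isoform and no vector control, so the isoform, the line, the sort and the vector cannot be separated. The p-values measure the spread between replicate cultures within a line, pooled over the 4 groups in the main fit. They do not measure how far separately made lines of an isoform would differ. The pooled spreads were unequal: the mean squared log2 deviation from the group was at most 0.0693 in control libraries and 0.243 in SEPT9_v3 replicate C.

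The authors deposited a table of 57445 genes by 12 libraries, whose values are a signal: gene counts divided by 1 size factor per library. CASAVA, Bowtie, DESeq and the human build hg19 are named, without versions, per the submitters' processing notes. The counting program, its strand setting and the gene annotation are not given in the sources used here. In each library 100 percent of the deposited values were whole multiples of what 1 read was worth, within a tolerance of 0.01 reads, so read counts could be recovered. These totalled 36415481 to 121948411 reads per library in control, 37887804 to 51271643 in SEPT9_v1, 61770924 to 69501362 in SEPT9_v2 and 52482654 to 61228844 in SEPT9_v3. Reads carried no molecular identifiers, so counting intervals cover counting error only.

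Gene symbols were looked up by gene identifier in tables of the GRCh38 assembly, and 51488 of the 57445 identifiers had one. Because that is another build than the one used for the files, no coordinates are given. Older symbols were matched through the same tables. SEPT9 and its relatives are written with their older symbols (SEPT9 for SEPTIN9). Genes that share reads with a near-identical copy, pseudogenes and antisense genes are reported as uncertain, since the counting could split or merge them. No read in a gene total can be assigned to the endogenous gene or to the transgene.

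Main test. The 16597 genes with a mean value of at least 10 over the 12 libraries, which held 99.95 percent of the normalised counts, were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1). One fit over all 12 libraries had a coefficient per group and no replicate block, and eBayes used a mean-variance trend. Each isoform was compared with control and with each other isoform, a moderated F test asked for any difference among the 4 groups, and p-values were adjusted by Benjamini-Hochberg within each comparison. A gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(value + 1) scale, where the added 1 makes changes of low genes smaller. Averages of logs can still give a larger fold than read totals, as for TBX15 in SEPT9_v1 against control (32-fold, read ratio 25). Values are given as mean ± SD of the deposited normalised counts with n = 3. Of 38 gene lists, 37 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data. None of the 55 list calls held with an estimated correlation. Of 1337 list members, 1318 were found in the table.

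Genes were named by a rule. Every tested septin fell under it, though values against control are given below only for SEPT9 and SEPT4. In each comparison with control, the rule took the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 100 in the higher group and no overlap between the 3 replicates of both groups, plus up to 4 called members per list. Between isoforms it took the 5 largest in each direction. Genes called in the same direction against control in all 3 lines were to be named if their mean was at least 100 in the higher group of each. The grouping, the design, the lists, this rule and most alternatives were fixed before the data were examined. Members of lists without called genes are named with their values.

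Alternatives were other pseudocounts (0.5 and 5), no filter or a mean of at least 50, upper-quartile, quantile and recomputed median-of-ratios scaling, eBayes without trend or robust, a replicate block, a fit of only the 2 groups compared, and leaving out each library in turn. The recovered reads were tested with edgeR 4.0.16 (TMM, quasi-likelihood) and DESeq2 1.42.0. In the comparisons with control edgeR called 3, 23 and 91 genes for SEPT9_v1, SEPT9_v2 and SEPT9_v3. Another 4 were chosen after the data were seen: leaving out the 3 libraries farthest out on the first principal component, a loess correction of each library for GC content and transcript length (available for 97.4 percent of tested genes), 1 surrogate variable from sva 3.50.0, and limma's library weights, whose estimation stopped before it converged.

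The test was run on simulated counts drawn for the 16597 genes from the real means, depths and dispersions, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were taken from those with a mean of at least 100, so their recovery does not cover lower genes. Of the genes changed 2-fold, 53, 42 and 54 were called in the right direction in the simulated comparisons of SEPT9_v1, SEPT9_v2 and SEPT9_v3 with control. Of those changed 4-fold, 100, 99 and 99 were. Among the unchanged genes 11, 9 and 10 were called, and 0 of 20 unchanged lists were called in each comparison. With a planted list of smaller changes, 167, 150 and 166 genes were called in all, against 7, 17 and 72 in the real data. More calls loosen the Benjamini-Hochberg cutoff, so the recovered shares may be too high for the real comparisons. Each gene was drawn independently, without the differences between libraries that many genes share in the real data. The simulation therefore does not measure how many lists would be called falsely there. Replicates were compared by a chi-square test of their recovered reads, and every pair differed by more than sampling noise, so each library counts as 1 replicate. A first version of the symbol lookup assigned a few list members to other genes. This was corrected after the list results had been seen, and it left the number of lists called in each comparison as it was. Figures were drawn with matplotlib 3.10.9.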

Results

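To ask how each of 3 SEPT9 isoforms changes gene expression in breast cancer cells, RNA was sequenced from MCF-7 cells without a vector and from 3 MCF-7 lines that each stably expressed a GFP fusion of SEPT9_v1, SEPT9_v2 or SEPT9_v3. SEPT9 encodes a septin, a GTP-binding protein that assembles into filaments, and its long isoforms differ at their amino termini. Each of the 4 groups held 3 replicate cultures. The libraries held 36415481 to 121948411 reads assigned to genes, the fewest in control replicate B and the most in control replicate C. Values are size factor-normalised read counts, and 16597 genes were tested.

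SEPT9 (ENSG00000184640.13) was measured first, as a check on the labels. Its normalised read count was 31830 ± 2863 in control (SD, n = 3), 75256 ± 18020 in SEPT9_v2, 51741 ± 21460 in SEPT9_v3 and 34673 ± 7928 in the libraries labelled SEPT9_v1. The SEPT9_v2 mean was 2.36 times that of control, with all 3 libraries above the control libraries, but the difference missed the threshold over all genes (log2 fold change 1.22 ± 0.28 SE, 95% confidence interval of the fold 1.54 to 3.52, limma adjusted p = 0.182). The SEPT9_v3 mean was 1.63 times that of control (fold interval 1.02 to 2.33, limma adjusted p = 0.407). In SEPT9_v3 replicate B the value of 32479 lay within the control range of 29466 to 35013. In the libraries labelled SEPT9_v1 the total was not called higher (1.09 times control, fold interval 0.709 to 1.62, limma adjusted p = 0.962), so the label of that line is not borne out by the gene total, and every direction given for it below is that of the libraries so labelled. The gene total does not separate isoforms or transgene from endogenous reads. DESeq2 on the recovered reads called the SEPT9_v2 difference (log2 fold change 1.24, DESeq2 adjusted p = 0.00703).

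**Figure D1:**
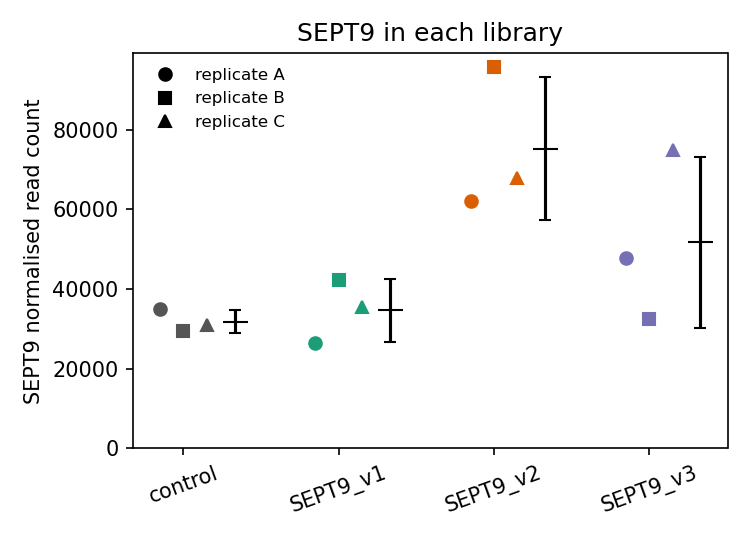
SEPT9 normalised read count (y axis) in each library of the 4 groups (x axis). Points are replicates, and the bars give the mean and SD of 3 replicates. All 3 SEPT9_v2 libraries lie between 62009 and 95778, above the control libraries, while SEPT9_v1 replicate A at 26412 lies below them.

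None of the 10 tested septins was called in any comparison with control. SEPT4 stood at 26.1 ± 5.44 in control and at 49.7 ± 5.7, 50.3 ± 7.58 and 54 ± 1.71 in the SEPT9_v1, SEPT9_v2 and SEPT9_v3 lines, with limma adjusted p of 0.474, 0.397 and 0.129. Adjusted over the list alone, 1 septin was higher in SEPT9_v1 and 2 in SEPT9_v3, while in SEPT9_v2 2 were higher and 1 was lower. The septin list as a whole was not called in any of the 3 (camera adjusted p = 0.758, 0.808 and 0.292).

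The libraries differed within groups. The first principal component carried 40% of the variance, and SEPT9_v1 replicate A, SEPT9_v2 replicate B and SEPT9_v3 replicate C lay farthest out on it. A library's place on it went with the GC content of genes. Across genes, which are not independent replicates, the Spearman correlation of log2 deviation with GC content was −0.622 in SEPT9_v1 replicate A, 0.627 in SEPT9_v2 replicate B and 0.668 in SEPT9_v3 replicate C, against −0.271 to −0.135 in control. Other isoform libraries showed it too, with −0.509 in SEPT9_v3 B, 0.488 in SEPT9_v2 C, −0.339 in SEPT9_v1 C and 0.283 in SEPT9_v1 B. SEPT9_v2 A (−0.115) and SEPT9_v3 A (−0.246) lay in or near the control range. Mitochondrially encoded genes took 2.25% of reads in SEPT9_v1 replicate A, against 5.08% and 4.36% in the other SEPT9_v1 libraries and 5.13% to 6.1% in control.

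**Figure D2:**
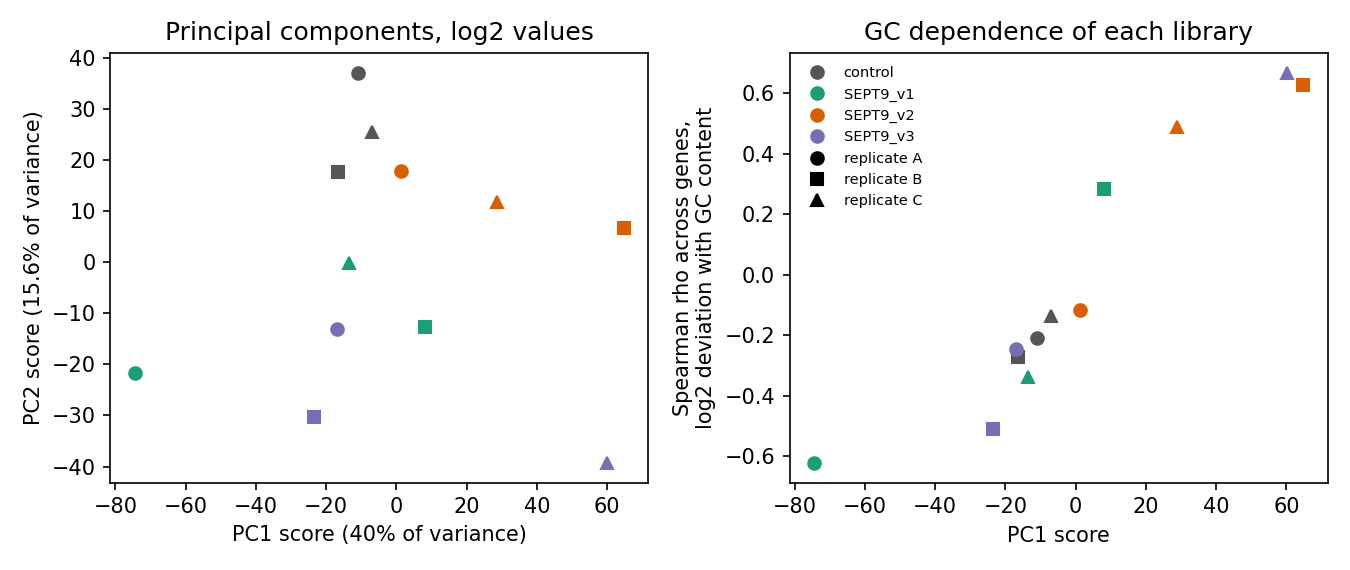
Left, scores of the 12 libraries on principal components 1 and 2 of the log2 values (40% and 15.6% of the variance). Right, the score on component 1 (x axis) against the Spearman correlation, across genes, of each library's log2 deviation with GC content (y axis). Colours are groups and shapes are replicates. SEPT9_v1 replicate A lies at the negative end of both axes of the right panel, and SEPT9_v2 replicate B and SEPT9_v3 replicate C at the positive end.

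SEPT9_v1 against control. In the libraries labelled SEPT9_v1, 4 genes were called higher than in control and 3 lower, a count that changed with the setting. TBX15 (ENSG00000092607.9), a T-box transcription factor, rose from 4.56 ± 4.05 to 131 ± 47.1 (log2 fold change 5.00 ± 0.678 SE, limma adjusted p = 0.0127). In reads this was 324 against 22, a ratio of 25 (95% counting interval 16.2 to 40.5). VCAN (ENSG00000038427.11), which encodes the matrix proteoglycan versican, rose from 7.68 ± 1.97 to 53 ± 25.7 (log2 fold change 2.55 ± 0.336, limma adjusted p = 0.0127). Both class II genes called fell: HLA-DPA1 from 72.2 ± 26 to 12.3 ± 6.09 (limma adjusted p = 0.0439) and HLA-DQA1 from 27.1 ± 7.92 to 3.43 ± 1.72 (limma adjusted p = 0.0439), with counts that are uncertain because HLA genes resemble each other. The reads behind them were 30 against 316 for HLA-DPA1, 6.2 times fewer (95% counting interval 4.26 to 9.35), and 8 against 97 reads for HLA-DQA1, 7.14 times fewer (3.48 to 17). The remaining 3 called genes fall outside the rule for naming and were chosen after their values were seen. They were GPC6, a glypican (60.1 against 1.24, limma adjusted p = 0.0115), SEMA5B, a semaphorin (17.3 against 73.8, limma adjusted p = 0.0439), and ENSG00000143140.6, which has no symbol in the tables used (14.4 against 0.284, limma adjusted p = 0.0439). The read ratio was 60.3 (95% counting interval 23 to 224) for GPC6 and 28.9 (7.4 to 248) for ENSG00000143140.6, which rested on 34 reads against 2.

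The count of 7 genes varied. It was 2 to 6 when any of the 6 libraries was left out (3, 3 and 2 without control A, B or C, and 4, 6 and 3 without SEPT9_v1 A, B or C), 0 in a fit of these 2 groups alone (limma adjusted p = 0.194 for VCAN and TBX15, 0.208 for HLA-DPA1 and 0.201 for HLA-DQA1), 2 among genes with a mean of at least 50, 3 with a replicate block and 3 with edgeR. It was higher with DESeq2 on the recovered reads (62), after the GC and length correction (60), without the 3 outlying libraries (114) and with 1 surrogate variable (357). VCAN was no longer called without control B (log2 fold change 2.38, limma adjusted p = 0.0584) or C (2.565, 0.0632) and TBX15 without SEPT9_v1 C (4.74, 0.0707). Each HLA gene kept its call in 1 of 6 such fits, with log2 fold changes of −2.85 to −2.05 for HLA-DPA1 and −2.98 to −2.47 for HLA-DQA1. With all libraries the HLA-DPA1 call ended without a filter on low genes (limma adjusted p = 0.119), among genes with a mean of at least 50 (0.0745), without a variance trend (0.0598), with a replicate block (0.0724) and with edgeR (edgeR adjusted p = 0.0502). The HLA-DQA1 call ended without a filter (limma adjusted p = 0.147), with a pseudocount of 5 (0.0548), with quantile normalisation (0.103), with a replicate block (0.0856) and with edgeR (edgeR adjusted p = 0.0822). In the fits without a library where a call of these 4 genes ended, the log2 fold change was 0.82 to 1.13 times that with all libraries.

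Among the gene lists, 6 shifted upward and 4 downward in the libraries labelled SEPT9_v1. DNA replication genes stood higher in 45 of 47 tested members (median log2 fold change 0.48, camera adjusted p = 4.21e-14, adjusted p = 0.648 with an estimated correlation), though none passed singly, over all genes or adjusted over the list alone. CDC45, a helicase component, stood at 3821 against 2324, and GINS2 at 9542 against 6082. Nuclear-encoded oxidative phosphorylation genes were higher in 47 of 50 (median 0.265, camera adjusted p = 1.27e-07, adjusted p = 0.652 with an estimated correlation). Ribosomal protein genes were higher in 45 of 57 (median 0.102, camera adjusted p = 0.00815, adjusted p = 0.749 with an estimated correlation). Mitosis genes were higher in 37 of 44 (median 0.227, camera adjusted p = 0.00101, adjusted p = 0.652 with an estimated correlation), among them MAD2L1 at 2913 against 1380. Cholesterol biosynthesis genes (median 0.325, camera adjusted p = 0.00231, adjusted p = 0.652 with an estimated correlation) and heat shock and metallothionein genes (median 0.252, camera adjusted p = 0.000122, adjusted p = 0.648 with an estimated correlation) also shifted upward. Adjusted over the list alone, 1 cholesterol gene passed and went the other way, PCSK9, which targets the LDL receptor for degradation (2.31 against 18.8).

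Extracellular matrix genes were lower in all but 3 of 33 members (median −0.381, camera adjusted p = 2.81e-06, adjusted p = 0.648 with an estimated correlation). The only member called rose, VCAN, while COL5A1 stood at 7044 against 12990 and FBN1 at 37.3 against 78.7. Antigen presentation genes shifted downward (median −0.148, camera adjusted p = 0.00092, adjusted p = 0.652 with an estimated correlation), with 2 members fallen over all genes and 5 adjusted over the list alone. The latter were HLA-DPA1, HLA-DQA1, HLA-DRA (33.8 against 163.8), the invariant chain gene CD74 (201.7 against 1053) and CIITA, the class II transactivator (55.3 against 189). Receptor tyrosine kinase and growth factor genes shifted downward (median −0.193, camera adjusted p = 0.00115, adjusted p = 0.648 with an estimated correlation), and 4 passed adjusted over the list alone: EPHA4, IGFBP5, AXL and IGFBP3. All 15 mitochondrially encoded genes were lower (median −0.629, camera adjusted p = 2.81e-06, adjusted p = 0.652 with an estimated correlation). Without SEPT9_v1 replicate A, 4 lists were called in place of 10, and mitosis turned (median −0.007, camera adjusted p = 0.759). The antigen presentation median came to −0.004 (camera adjusted p = 0.0611), and the medians of mitochondrially encoded genes (−0.256, camera adjusted p = 0.265), cholesterol (0.124, 0.195), heat shock (0.128, 0.0611) and receptor tyrosine kinases (−0.122, 0.0536) were also nearer to 0 and not called. Without the 3 outlying libraries these 6 medians were as without SEPT9_v1 A, and the antigen presentation and cholesterol (both camera adjusted p = 0.147), receptor tyrosine kinase and heat shock (both 0.0619) and mitochondrial (0.31) calls ended. The ribosomal call ended with about the same median without control B (0.092, camera adjusted p = 0.0705) and after the GC and length correction (0.101, 0.0856), and with a smaller one without SEPT9_v1 B (0.009, 0.31) or C (0.049, 0.151) and with quantile normalisation (0.019, 0.631).

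SEPT9_v2 against control. In the SEPT9_v2 line 14 genes were higher and 3 lower. VCAN rose from 7.68 ± 1.97 to 685.8 ± 71.9 (log2 fold change 6.33 ± 0.336 SE, limma adjusted p = 1.23e-07). SOX2, a transcription factor of stem and progenitor cells, fell from 102.6 ± 14.7 to 10.9 ± 2.13 (log2 fold change −3.13 ± 0.308, limma adjusted p = 0.000337). RAB34, a small GTPase, rose from 23.2 ± 7.61 to 187 ± 50.2 (log2 fold change 2.98 ± 0.418, limma adjusted p = 0.0115), and the membrane-type metalloproteinase MMP24 from 75.5 ± 19.6 to 376 ± 140 (log2 fold change 2.28 ± 0.383, limma adjusted p = 0.0313). SLC17A9, a vesicular nucleotide transporter, was 4.71-fold higher, the keratin gene KRT13 4.22-fold, THRSP, which acts in lipid synthesis, 3.99-fold, and CALB2, which encodes calretinin, 3.1-fold. The alpha-tubulin genes TUBA3D and TUBA3E were 4.26-fold and 4.01-fold higher, and cannot be told from each other with confidence because they are near-identical. IGFBP3, an insulin-like growth factor binding protein, fell from 176 ± 13.8 to 48.1 ± 19.9, and SHISA2 from 1658 ± 293 to 691 ± 64.1. Leaving out any of the 6 libraries gave 2 to 9 genes in place of 17 (3, 4 and 3 without control A, B or C, and 9, 3 and 2 without SEPT9_v2 A, B or C). VCAN and SOX2 were called in all 6 of those fits, with log2 fold changes of 6.15 to 6.49 for VCAN and −3.24 to −2.98 for SOX2, RAB34 in 2 of 6 (2.69 to 3.20), and the others named here in 1 or 0 of 6. The genes that lost calls kept log2 fold changes of 0.8 to 1.12 times those with all libraries, for example 1.92 to 2.05 for THRSP, 1.90 to 2.14 for TUBA3E and 2.11 to 2.45 for SLC17A9. With the same folds, calls ended without a filter on low genes for MMP24 (limma adjusted p = 0.0714), SLC17A9, TUBA3E and CALB2 (each 0.108), KRT13 and SHISA2 (both 0.0506) and IGFBP3 (0.0663). They ended without a variance trend for MMP24, TUBA3E and SHISA2 (each 0.0675) and KRT13 (0.075). The count of 17 was 8 without a filter on low genes, and it was higher with a pseudocount of 5 (26), quantile normalisation (28), 1 surrogate variable (58), the GC and length correction (61), DESeq2 (95), a fit of these 2 groups alone (181) and without the 3 outlying libraries (83).

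In SEPT9_v2, 5 lists shifted upward and 4 downward. Oxidative phosphorylation genes were higher in 44 of 50 (median log2 fold change 0.388, camera adjusted p = 2.2e-07, adjusted p = 0.832 with an estimated correlation), for example NDUFB7 at 15520 against 8159. Ribosomal protein genes were higher in 43 of 57 (median 0.206, camera adjusted p = 0.00953, adjusted p = 0.89 with an estimated correlation), but with quantile normalisation their median was −0.097 (camera adjusted p = 0.152), and after the GC and length correction the call ended (median 0.105, camera adjusted p = 0.141). Antigen presentation genes, which shifted downward in the libraries labelled SEPT9_v1, were higher in 19 of 23 (median 0.319, camera adjusted p = 0.00918, adjusted p = 0.89 with an estimated correlation), with HLA-DRB1 at 1357 against 627 the only member past the test adjusted over the list alone. Estrogen receptor target genes (median 0.141, camera adjusted p = 0.035, adjusted p = 0.608 with an estimated correlation) held 1 called member, KRT13. Adjusted over the list alone 3 rose, KRT13, HSPB8 and AGR2, and CXCL12 fell (112 against 227). Hypoxia-inducible genes shifted upward (median 0.256, camera adjusted p = 0.0385, adjusted p = 0.53 with an estimated correlation), with the glycolytic gene ALDOC at 1498 against 643 passing adjusted over the list alone.

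Mitosis genes were lower in all but 10 of 44 (median −0.271, camera adjusted p = 0.00918, adjusted p = 0.89 with an estimated correlation), for example AURKA at 6512 against 9430. TGF-beta and BMP targets shifted downward (median −0.168, camera adjusted p = 0.0117, adjusted p = 0.53 with an estimated correlation), with the cell cycle inhibitor CDKN2B at 103 against 263. Genes of both MCF-7 amplicons shifted downward, those on chromosome arm 20q (median −0.224, camera adjusted p = 0.035, adjusted p = 0.755 with an estimated correlation) and those on 17q (median −0.352, camera adjusted p = 0.0103, adjusted p = 0.89 with an estimated correlation), the latter list holding SEPT9 itself. Both amplicon calls ended after the GC and length correction, with smaller medians on 20q (−0.141, camera adjusted p = 0.0984) and 17q (−0.126, 0.202). The 20q call also ended without control A, where the median stayed at −0.224 (camera adjusted p = 0.0617), among genes with a mean of at least 50 (−0.197, 0.0756) and with a median of −0.137 both without SEPT9_v2 B (0.0596) and without the 3 outlying libraries (0.0522). Without control B the calls of mitosis (median −0.158, camera adjusted p = 0.0822), antigen presentation (0.181, 0.0538) and estrogen receptor targets (0.179, 0.0675) ended, the last with a larger median. The estrogen receptor call ended as well without control C (0.123, 0.0588) or SEPT9_v2 A (0.082, 0.211) and with quantile normalisation (0.089, 0.331). The hypoxia call ended with the same median among genes with a mean of at least 50 (0.256, camera adjusted p = 0.0554), and with smaller ones without control C (0.185, 0.135), SEPT9_v2 A (0.211, 0.216) or SEPT9_v2 C (0.198, 0.0884).

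SEPT9_v3 against control. The SEPT9_v3 line differed in the most genes of the 3 in this fit, 55 higher and 17 lower. Several were almost silent in control. GPC6 (ENSG00000183098.6), a cell surface heparan sulfate proteoglycan, rose from 1.24 ± 1.47 to 316 ± 45.6 (log2 fold change 7.35 ± 0.607 SE, limma adjusted p = 1.56e-05), or 967 reads against 4, a ratio of 326 (95% counting interval 127 to 1200). ECEL1, an endothelin-converting enzyme relative, rose from 2.42 ± 2.11 to 212 ± 125 and VCAN from 7.68 ± 1.97 to 259 ± 80.4 (log2 fold change 4.89 ± 0.336, limma adjusted p = 2.45e-06). The transcription factor genes ZIC1 and SOX11 rose from 3.47 ± 3.05 to 158 ± 18.6 and from 4.66 ± 2.66 to 145 ± 26.5. SLFN11, NLRX1 and the arylsulfatase gene ARSJ rose likewise. These genes had 12 to 26 reads in control. Their read ratios were 68.5 (95% counting interval 38.9 to 133) for ECEL1, 42.8 (25.7 to 77) for ZIC1, 32.6 (20.4 to 55.4) for SOX11, 40.5 (22.9 to 79.1) for SLFN11, 33 (20.9 to 55.4) for NLRX1 and 31.6 (21.3 to 48.7) for ARSJ. Among the falls, ALDH1L2, a mitochondrial folate enzyme, went from 812 ± 370 to 142 ± 17.6 (log2 fold change −2.41 ± 0.385, limma adjusted p = 0.00962) and the lipid transporter gene ABCA12 from 4520 ± 656 to 1631 ± 356. FILIP1L (2.83-fold), CDKN2B (2.4-fold), TRANK1 (2.4-fold) and HMCN1, a matrix protein gene (2.34-fold), also fell. PHF2P2, a pseudogene, and SOCS2-AS1, an antisense transcript, fell 3.63-fold and 3.11-fold and are uncertain. Leaving out any of the 6 libraries gave 25 to 69 genes in place of 72 (25, 44 and 26 without control A, B or C, and 69, 35 and 45 without SEPT9_v3 A, B or C). GPC6, ECEL1, ZIC1, SLFN11, VCAN, NLRX1 and ARSJ were called in all 6 fits, ABCA12 in 4, ALDH1L2 in 3, SOCS2-AS1 in 2, each of SOX11, PHF2P2, FILIP1L, TRANK1 and HMCN1 in 1, and CDKN2B in 0. The folds of those that lost calls stayed near their values with all libraries, with log2 ranges of 4.55 to 5.13 for SOX11, −1.39 to −1.14 for CDKN2B, −1.43 to −1.14 for TRANK1 and, the widest of these relative to its value, −2.29 to −1.53 for PHF2P2. With the same folds, the CDKN2B call ended without a filter on low genes (limma adjusted p = 0.0776), among genes with a mean of at least 50 (0.0573), without a variance trend (0.0549) and with robust eBayes (0.0503). Those of PHF2P2 and SOCS2-AS1 ended without a filter (both 0.0579). The count of 72 was 47 among genes with a mean of at least 50, 332 with DESeq2, 518 after the GC and length correction, 542 without the 3 outlying libraries and 1093 with 1 surrogate variable.

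**Figure D3:**
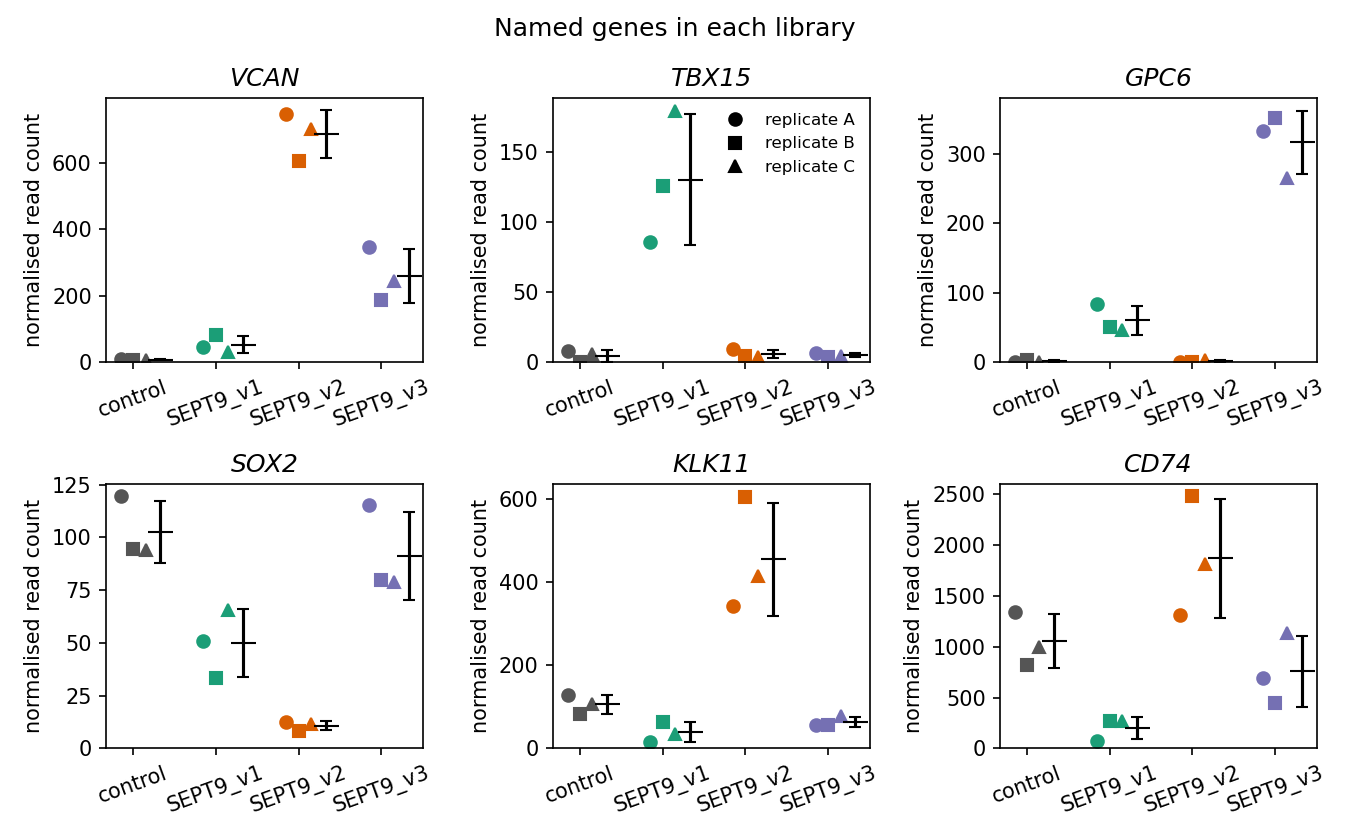
Normalised read count (y axes, each with its own scale from 0) of VCAN, TBX15, GPC6, SOX2, KLK11 and CD74 in each library of the 4 groups. Points are replicates, and the bars give the mean and SD of 3 replicates. VCAN was 7.68 in control and 685.8 in SEPT9_v2, TBX15 reached 131 in SEPT9_v1, and GPC6 reached 316 in SEPT9_v3.

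In SEPT9_v3, 7 lists shifted upward and 5 downward. DNA replication genes were higher in 44 of 47 (median log2 fold change 0.343, camera adjusted p = 1.46e-08, adjusted p = 0.483 with an estimated correlation). Of these GINS2 rose (11940 against 6082, limma adjusted p = 0.0467), and 8 passed adjusted over the list alone, among them the thymidine kinase gene TK1 at 21790 against 10430. Oxidative phosphorylation genes were higher in 45 of 50 (median 0.367, camera adjusted p = 1e-06, adjusted p = 0.483 with an estimated correlation). Ribosomal protein genes were higher in 52 of 57 (median 0.209, camera adjusted p = 0.00672, adjusted p = 0.783 with an estimated correlation), with a median of −0.041 under quantile normalisation (camera adjusted p = 0.685). Basal and myoepithelial markers shifted upward (median 0.184, camera adjusted p = 0.00672, adjusted p = 0.483 with an estimated correlation). The keratin gene KRT16 rose from 120.4 ± 6.26 to 548.3 ± 318 (limma adjusted p = 0.0437), although its close relatives make the count uncertain, and ACTG2, KRT15 and ID4 passed with it adjusted over the list alone. Cholesterol biosynthesis genes were higher in 23 of 29 (median 0.275, camera adjusted p = 0.00567, adjusted p = 0.483 with an estimated correlation). Actin regulators (median 0.118, camera adjusted p = 0.0363, adjusted p = 0.483 with an estimated correlation) included LCP1, an actin-bundling plastin, which rose from 1643 ± 128 to 3076 ± 507. Heat shock and metallothionein genes shifted upward (median 0.147, camera adjusted p = 0.0363, adjusted p = 0.483 with an estimated correlation).

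Extracellular matrix genes were lower in all but 8 of 33 (median −0.224, camera adjusted p = 0.0132, adjusted p = 0.712 with an estimated correlation). VCAN rose, COL4A5, a basement membrane collagen chain, fell from 2604 ± 252 to 1395 ± 312 (limma adjusted p = 0.0467), and THBS1 and COL4A6 passed with COL4A5 adjusted over the list alone. Unfolded protein response genes (median −0.315, camera adjusted p = 0.00847, adjusted p = 0.483 with an estimated correlation) had 5 members lower and 1 higher adjusted over the list alone, among them DDIT3 at 146.3 against 362 and SDF2L1 at 2466 against 1315. The p53 targets (median −0.269, camera adjusted p = 0.0193, adjusted p = 0.483 with an estimated correlation), TGF-beta and BMP targets (median −0.271, camera adjusted p = 0.00595, adjusted p = 0.483 with an estimated correlation) and the 20q amplicon genes (median −0.256, camera adjusted p = 0.0363, adjusted p = 0.483 with an estimated correlation) shifted downward, with CDKN2B fallen among the TGF-beta targets. From lists that were not called, TGFB1I1, a focal adhesion protein gene, rose from 25.1 ± 4.94 to 232 ± 129, TAGLN, an actin-binding protein gene, from 56.7 ± 6.53 to 416 ± 266, DUSP4, a MAP kinase phosphatase gene, from 778 ± 82.1 to 1952 ± 205, RERG from 594 ± 31.6 to 1293 ± 311, the immunoproteasome gene PSMB9 from 12.7 ± 5.4 to 55.6 ± 28.3. The ephrin receptor gene EPHA4 fell from 4058 ± 850 to 2061 ± 193. Among the genes named from lists, TGFB1I1 and TAGLN kept their calls without any of the 6 libraries, DUSP4 in 4 of 6 such fits, GINS2 in 2, RERG, LCP1 and COL4A5 in 1, and KRT16, PSMB9 and EPHA4 in 0. With all libraries, calls ended without a filter on low genes for COL4A5 and LCP1 (both limma adjusted p = 0.0501), KRT16 (0.066), GINS2 (0.0728) and PSMB9 (0.12). They ended without a variance trend for RERG (0.0549), EPHA4 (0.0659), LCP1 (0.0742), COL4A5 (0.0747), KRT16 and GINS2 (both 0.0786). They ended with robust eBayes for KRT16 (limma adjusted p = 0.0502), COL4A5 and LCP1 (both 0.051) and GINS2 (0.0544). In a fit of these 2 groups alone they ended for EPHA4 (0.0892), LCP1 (0.105), GINS2 (0.107) and COL4A5 (0.108). Among genes with a mean of at least 50 KRT16 (0.0573) and GINS2 (0.0519) were not called, nor GINS2 with quantile normalisation (log2 fold change 0.87, 0.0617), nor LCP1 with upper-quartile scaling (0.0596). Over all named genes that lost calls without a library in this comparison, the log2 fold change without a library was 0.78 to 1.23 times that with all.

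Without SEPT9_v3 replicate A 6 lists were called in place of 12, though the medians of p53 targets (−0.322, camera adjusted p = 0.134), heat shock (0.208, 0.101) and 20q genes (−0.358, 0.0517) were larger than with all libraries, and those of the unfolded protein response (−0.296, 0.134) and actin lists (0.117, 0.0853) about as large. The basal median was smaller (0.12, 0.0757). Without control A the calls of p53 targets (median −0.224, camera adjusted p = 0.101), the unfolded protein response (−0.203, 0.0691) and 20q genes (−0.217, 0.0691) ended with smaller medians. Without control C those of actin (0.078, 0.157) and heat shock (0.081, 0.142) did, while the 20q call ended with about the same median (−0.258, 0.0511). Without SEPT9_v3 B the extracellular matrix median was 0.001 (camera adjusted p = 0.861) and the ribosomal median 0.121 (0.613), while the heat shock (0.172, 0.0858) and 20q calls (−0.253, 0.0584) ended with about the same medians or larger ones. Without SEPT9_v3 C the medians of ribosomal (0.063, camera adjusted p = 0.119), actin (0.048, 0.199) and 20q genes (−0.109, 0.18) were smaller, with the same 3 medians without the 3 outlying libraries (camera adjusted p = 0.106, 0.16 and 0.16), and the basal call ended with about the same median (0.172, 0.0587). After the GC and length correction the calls of the matrix (median −0.05, camera adjusted p = 0.167), ribosomal (0.126, 0.167), heat shock (0.193, 0.0964) and 20q lists (−0.107, 0.149) ended, the heat shock median being larger. With quantile normalisation the actin (0.019, 0.382) and heat shock (0.042, 0.237) calls ended, and among genes with a mean of at least 50 the heat shock (0.146, 0.0637) and 20q (−0.232, 0.0679) calls.

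Genes shared by the 3 lines. VCAN was the only gene called in the same direction in all 3 comparisons with control, 5.86-fold, 80.2-fold and 29.6-fold on the log2(value + 1) scale. Without control B or C no gene was, since the SEPT9_v1 call ended, nor in fits of only the 2 groups compared. The count was 2 without a variance trend, 3 after the GC and length correction, and 4 with DESeq2, with 1 surrogate variable or without the 3 outlying libraries. No gene was lower in all 3. GPC6 and ENSG00000143140.6 were called higher in the libraries labelled SEPT9_v1 and in SEPT9_v3. TMTC1 (1.14 in control, 46.3 in SEPT9_v2 and 65.8 in SEPT9_v3) and MGAT3, a glycosyltransferase gene (20.1, 69.8 and 73), were called higher in SEPT9_v2 and SEPT9_v3. TMTC1 had 8 reads in control, with read ratios of 23.9 (95% counting interval 11.8 to 56.3) in SEPT9_v2 and 34.1 (17 to 80) in SEPT9_v3. ENSG00000143140.6 had 2, with a ratio of 180 (49.4 to 1500) in SEPT9_v3. These were chosen after their values were seen, and VCAN did not meet the level asked by the rule for shared genes in the libraries labelled SEPT9_v1. The F test found a difference among the 4 groups for 134 genes. That count was 73, 79 and 76 without control A, B or C, 73 and 66 without SEPT9_v2 B or C, 82 and 86 without SEPT9_v3 A or B, 638 with DESeq2, 641 without the 3 outlying libraries, 706 after the GC and length correction and 898 with 1 surrogate variable.

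Because the 3 comparisons share the control libraries, their fold changes correlate without any effect. The correlation across genes was 0.215 between SEPT9_v1 and SEPT9_v2, 0.54 between SEPT9_v1 and SEPT9_v3 and 0.526 between SEPT9_v2 and SEPT9_v3. Unchanged simulated groups with 1 dispersion over all libraries, the simulation run first, gave 0.491, 0.489 and 0.5. With dispersions estimated separately for control and isoform libraries, a choice made after those values were seen, they gave 0.26, 0.262 and 0.267. The observed covariance exceeded the simulated by −0.0142, 0.0498 and 0.0564 in the first simulation and by 0.0162, 0.0799 and 0.0871 in the other, so its sign for SEPT9_v1 with SEPT9_v2 depended on the dispersions. Genes called higher in both numbered 1, 3 and 3, where independent lists would share 0.00337, 0.0133 and 0.0464. The 3 controls are too few to be split into parts of 2, and part of the excess may come from sharing them.

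SEPT9_v1 against SEPT9_v2. The libraries labelled SEPT9_v1 had 20 genes higher and 71 lower than SEPT9_v2. TBX15 was higher in SEPT9_v1 (131 ± 47.1 against 5.85 ± 3.13, limma adjusted p = 0.00862). Its read ratio was 21.9 (95% counting interval 14 to 36.4). Also higher were the smooth muscle actin gene ACTG2 (133 ± 53.4 against 14.4 ± 18.8), TAGLN (195.2 ± 82.1 against 43 ± 11.5), CNTNAP2 (133 ± 31.9 against 45.2 ± 17.1) and the guanylate cyclase gene GUCY1A2 (107.7 ± 30.3 against 34.8 ± 0.258). SLC17A9 was 14.8-fold lower in SEPT9_v1, with 15.1 times fewer reads (95% counting interval 10.1 to 23.5), VCAN 13.7-fold and the kallikrein gene KLK11 12.8-fold (38.8 ± 24.2 against 454.6 ± 136, limma adjusted p = 0.000402). CD74 was 10.4-fold lower (201.7 ± 112 against 1868 ± 582, limma adjusted p = 0.00216) and RAB34 9.55-fold. These 5 lower genes kept their calls without any of the 6 libraries, TBX15 and ACTG2 in 4 of 6 such fits, TAGLN in 3, and CNTNAP2 and GUCY1A2 in 2, with log2 fold changes of 0.85 to 1.01 times those with all libraries where a call ended. In a fit of these 2 groups alone ACTG2 (limma adjusted p = 0.107), TAGLN (0.0553), CNTNAP2 (0.135) and GUCY1A2 (0.0863) were not called. CNTNAP2 (0.0863) and GUCY1A2 (0.0624) were not without a filter on low genes, nor CNTNAP2 with 1 surrogate variable (log2 fold change 1.14, limma adjusted p = 0.0653). Antigen presentation genes were lower in all but 2 of 23 (median −0.422, camera adjusted p = 3.58e-07, adjusted p = 0.637 with an estimated correlation), 6 of them past the test over all genes and 8 adjusted over the list alone. Mitosis genes (41 of 44 higher, median 0.419, camera adjusted p = 3.58e-07, adjusted p = 0.637 with an estimated correlation) and DNA replication genes (39 of 47 higher, median 0.535, camera adjusted p = 9.8e-07, adjusted p = 0.637 with an estimated correlation) stood higher in SEPT9_v1. Extracellular matrix genes stood lower (median −0.548, camera adjusted p = 2.48e-05, adjusted p = 0.637 with an estimated correlation). Mitochondrially encoded genes (median −0.565, camera adjusted p = 0.000782, adjusted p = 0.637 with an estimated correlation) stood lower and the 17q amplicon genes (median 0.379, camera adjusted p = 0.00647, adjusted p = 0.637 with an estimated correlation) higher, and both calls ended with smaller medians without SEPT9_v1 A (−0.158 and 0.164, camera adjusted p = 0.239 and 0.132) and without the 3 outlying libraries (medians −0.067 and 0.052, camera adjusted p = 0.583 and 0.413). The 17q call also ended after the GC and length correction (median 0.237, camera adjusted p = 0.091). The count of 91 genes was 27 without SEPT9_v2 B or C, 50 without SEPT9_v1 A and 55 without SEPT9_v2 A. It was 23 in a fit of these 2 groups alone, 60 without a filter on low genes, 396 with DESeq2 and 548 after the GC and length correction.

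SEPT9_v1 against SEPT9_v3. Of 28 genes, 2 were higher in the libraries labelled SEPT9_v1, TBX15 (131 ± 47.1 against 5.18 ± 1.44, limma adjusted p = 0.0142) and the aldo-keto reductase gene AKR1C2 (4739 ± 1020 against 2125 ± 408, limma adjusted p = 0.0334), whose count is uncertain because of near-identical relatives. The TBX15 read ratio was 25.5 (95% counting interval 15.4 to 45.1). SOX11 was lower (7.28 ± 6.8 against 145 ± 26.5, limma adjusted p = 0.0212), with 21.6 times fewer reads (13.1 to 38.1). Also lower were NLRX1 (21.8 ± 8.1 against 157.6 ± 55.2), the kinase gene NEK9 (35.8 ± 3.43 against 206 ± 29.4), PEG10, an imprinted gene (135 ± 99.8 against 668 ± 214), and the antisense transcript TM4SF18-AS1 (450.8 ± 97.1 against 2910 ± 1010), which is uncertain. Without each of the 6 libraries in turn, TM4SF18-AS1 kept its call in 6 fits, NEK9 in 5, SOX11 and AKR1C2 in 3, TBX15 and PEG10 in 2 and NLRX1 in 0, with log2 fold changes of 0.86 to 1.09 times those with all libraries where a call ended. With a pseudocount of 0.5 TBX15 (limma adjusted p = 0.0534), SOX11 (0.0669) and NLRX1 (0.0624) were not called. NLRX1 was not called without a filter on low genes (0.0975) or with quantile normalisation (0.0883). AKR1C2 (0.0686) and PEG10 (0.054) lost their calls without a variance trend. AKR1C2 lost it also in a fit of these 2 groups alone (0.342) and after the GC and length correction (log2 fold change 0.97, limma adjusted p = 0.117). Basal markers (median −0.376, camera adjusted p = 4.23e-05, adjusted p = 0.254 with an estimated correlation), antigen presentation (median −0.24, camera adjusted p = 4.23e-05, adjusted p = 0.547 with an estimated correlation), mitochondrially encoded genes (median −0.597, camera adjusted p = 0.00011, adjusted p = 0.547 with an estimated correlation), neural markers (median −0.287, camera adjusted p = 0.00497, adjusted p = 0.254 with an estimated correlation) and mesenchymal markers (median −0.296, camera adjusted p = 0.00782, adjusted p = 0.532 with an estimated correlation) stood lower in SEPT9_v1. So did interferon-stimulated genes (median −0.189, camera adjusted p = 0.0177, adjusted p = 0.442 with an estimated correlation), luminal identity genes (median −0.314, camera adjusted p = 0.0177, adjusted p = 0.496 with an estimated correlation) and matrix proteases (median −0.187, camera adjusted p = 0.0437, adjusted p = 0.547 with an estimated correlation). The p53 targets (median 0.244, camera adjusted p = 0.00182, adjusted p = 0.397 with an estimated correlation) and mitosis genes (median 0.14, camera adjusted p = 0.0335, adjusted p = 0.698 with an estimated correlation) stood higher. Without SEPT9_v1 A the mitosis median was −0.094 (camera adjusted p = 0.165), and the mitochondrial (median −0.166, camera adjusted p = 0.35), mesenchymal (−0.126, 0.158), matrix protease (−0.1, 0.252), luminal (−0.14, 0.0774) and interferon (−0.106, 0.0557) calls ended with smaller medians. The interferon call also ended without SEPT9_v1 B (−0.2, 0.0518), with a median about as large. Without SEPT9_v3 A the mitosis (median 0.191, camera adjusted p = 0.0512), matrix protease (−0.232, 0.155) and luminal (−0.337, 0.0656) calls ended though their medians were larger, and without SEPT9_v3 C the same 3 with smaller medians (0.112, −0.001 and −0.112, camera adjusted p = 0.192, 0.306 and 0.055). Without the 3 outlying libraries the medians of antigen presentation (0.007), mitochondrially encoded genes (0.014) and matrix proteases (0.111) turned, and that of mitosis was called in the other direction (−0.163, camera adjusted p = 0.00539), while the neural (median −0.276, camera adjusted p = 0.117), mesenchymal (−0.148, 0.792), luminal (−0.042, 0.558) and interferon (−0.036, 0.378) calls ended, the neural median being about as large as before. The mitosis call also ended after the GC and length correction (0.064, 0.149) and with the same median among genes with a mean of at least 50 (0.14, 0.0692), and the matrix protease call with quantile normalisation (−0.139, 0.0626). The count of 28 genes was 2 without SEPT9_v3 A, 13 or 14 without SEPT9_v1 B, SEPT9_v1 C or SEPT9_v3 C, 13 among genes with a mean of at least 50, and 18 and 49 with pseudocounts of 0.5 and 5. It was 116 without the 3 outlying libraries, 125 with DESeq2, 140 with 1 surrogate variable and 172 after the GC and length correction.

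SEPT9_v3 against SEPT9_v2. SEPT9_v3 had 66 genes higher and 27 lower than SEPT9_v2. GPC6 stood at 316 ± 45.6 against 1.28 ± 2.22 (limma adjusted p = 2.2e-05), a read ratio of 260 (95% counting interval 101 to 956). SOX11 stood at 145 ± 26.5 against 0.526 ± 0.911 (limma adjusted p = 0.000417), or 434 reads against 2, a ratio of 233 (95% counting interval 64.2 to 1930). ECEL1, ARSJ and ZIC1 were higher with read ratios of 164 (63.6 to 603), 81.7 (41.2 to 190) and 63.8 (32.1 to 149). RAB34 was 11.3-fold lower in SEPT9_v3, SLC17A9 10.8-fold, KLK11 6.92-fold, SULF1, a heparan sulfate sulfatase gene, 5.55-fold (310.8 ± 78.4 against 1708 ± 281) and MMP24 5.2-fold. MMP24 kept its call in 3 of the 6 fits without a library (log2 fold changes of −2.79 to −2.09) and the other 9 in all 6. DNA replication genes (median 0.407, camera adjusted p = 7.33e-09, adjusted p = 0.762 with an estimated correlation), mitosis genes (42 of 44 higher, median 0.311, camera adjusted p = 1.17e-05, adjusted p = 0.813 with an estimated correlation), cholesterol biosynthesis genes (median 0.244, camera adjusted p = 0.00282, adjusted p = 0.801 with an estimated correlation) and basal markers (median 0.212, camera adjusted p = 0.0217, adjusted p = 0.762 with an estimated correlation) stood higher in SEPT9_v3. Among the basal markers ID4, ACTG2 and KRT16 were higher and CAV1 lower. Extracellular matrix genes (median −0.357, camera adjusted p = 6.2e-05, adjusted p = 0.762 with an estimated correlation), p53 targets (median −0.275, camera adjusted p = 0.000115, adjusted p = 0.596 with an estimated correlation), unfolded protein response genes (median −0.184, camera adjusted p = 0.000573, adjusted p = 0.762 with an estimated correlation) and antigen presentation genes (median −0.234, camera adjusted p = 0.00215, adjusted p = 0.929 with an estimated correlation) stood lower. Without SEPT9_v3 C the basal median was −0.078 (camera adjusted p = 0.553) and the cholesterol call ended (median 0.123, camera adjusted p = 0.249). With smaller medians, the basal call ended without SEPT9_v2 A (0.104, 0.208) and among genes with a mean of at least 50 (0.163, 0.126), the matrix call without SEPT9_v3 B (−0.052, 0.196), and the antigen presentation call without SEPT9_v2 B (−0.155, 0.112), SEPT9_v3 A (−0.149, 0.0837) or B (−0.177, 0.0507). Without the 3 outlying libraries the basal (median 0.071, camera adjusted p = 0.148) and cholesterol (0.124, 0.0695) calls ended. The count of 93 genes was 45 to 57 without any of the other 5 libraries and 140 without SEPT9_v3 C. It was 58 among genes with a mean of at least 50, 259 with DESeq2, 348 after the GC and length correction, 454 with 1 surrogate variable and 571 without the 3 outlying libraries.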

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

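The tests of depth, of GC content and length, of a swap, of transgene level and of fibroblasts were chosen or reworded after the results they bear on had been seen. Differences between the lines were tested directly, as contrasts in 1 limma fit, since each is the difference of effects against the same control. They gave 91 genes for SEPT9_v1 against SEPT9_v2, 28 for SEPT9_v1 against SEPT9_v3 and 93 for SEPT9_v3 against SEPT9_v2. Groups of 3 are too small for a test of single outlying samples.

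On the log2 scale, SEPT9_v1 exceeded SEPT9_v2 by 4.29 for TBX15, 3.81 for ACTG2, 2.11 for TAGLN, 1.57 for CNTNAP2 and 1.57 for GUCY1A2, and the difference was −3.89 for SLC17A9, −3.77 for VCAN, −3.68 for KLK11, −3.38 for CD74 and −3.26 for RAB34. SEPT9_v1 exceeded SEPT9_v3 by 4.38 for TBX15 and 1.16 for AKR1C2, and the difference was −4.82 for SOX11, −2.81 for NLRX1, −2.66 for TM4SF18-AS1, −2.49 for NEK9 and −2.48 for PEG10. SEPT9_v3 exceeded SEPT9_v2 by 7.54 for GPC6, 6.79 for ECEL1, 6.72 for SOX11, 5.79 for ARSJ and 5.52 for ZIC1, and the difference was −3.49 for RAB34, −3.43 for SLC17A9, −2.79 for KLK11, −2.47 for SULF1 and −2.38 for MMP24.

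SEPT9_v1 replicate A, SEPT9_v2 replicate B and SEPT9_v3 replicate C, each the library of its line farthest out on the first component, had a mean squared log2 deviation from their own groups of 0.227, 0.123 and 0.243, against at most 0.0693 in a control library. SEPT9_v1 B at 0.142 and SEPT9_v3 B at 0.165 deviated more than SEPT9_v2 B. SEPT9_v3 A (0.11), SEPT9_v2 A (0.0994) and SEPT9_v1 C (0.0857) also lay above the control libraries, and of the isoform libraries only SEPT9_v2 C (0.0477) did not. Each deviation is taken from a group mean that includes the outlying library, which also raises the values of its group mates. The log2 correlation was 0.9881 for SEPT9_v1 B with C, 0.9909 for SEPT9_v2 A with C and 0.9835 for SEPT9_v3 A with B. Between control libraries it was 0.9883 to 0.9939. The chi-square per gene was 35.09, 64.55 and 192.2 for these pairs, against 25.22 to 36.98 in control. An excess among group mates was thus clearest in SEPT9_v3, and these pairs do not show one in SEPT9_v1. Depth is argued against, since with every library thinned to the lowest depth the smallest of the 3 was 0.143 and the farthest control library 0.074. GC content and gene length carried part of it, but the corrected values of 0.153 in SEPT9_v1 A and 0.119 in SEPT9_v3 C stayed above the control mean plus 2 SD of 0.0882, which argues against that bias as their whole cause. For SEPT9_v2 B it stays open: its corrected value of 0.0821 lay under that bound, but above the farthest control library at 0.0685, a stricter bound that was used first and replaced after the values were seen. The corrected values of SEPT9_v1 B (0.0959) and SEPT9_v3 B (0.089) lay above 0.0882 as well, with the same limit from the shared group mean. A SEPT9 dose that differs between cultures of a line also stays open, because SEPT9 moved along the first component at percentile 64.5 of 152 genes matched on GC content, length and level, which neither requires nor rules it out.

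SEPT9 was not called higher in the libraries labelled SEPT9_v1. GC content and length hiding a rise like that of SEPT9_v2 is argued against, since the corrected log2 difference from control was 0.237 ± 0.13 (SE) against 1.03 in SEPT9_v2. A swap of 1 or 2 libraries each with control is argued against, since every regrouping of the 6 libraries that undoes such a swap called 0 genes, against 7 as labelled. The contrast is small, because the labelled grouping itself called 0 in a fit of these 2 groups alone. A swap of all 3 stays open: the libraries labelled control held less SEPT9 on average (31830 against 34673), which goes against it but within the spread, and the highest of them at 35013 lay below the lowest SEPT9_v2 library at 62009, a bound used first, but above SEPT9_v3 replicate B at 32479. A transgene expressed too low to raise the total, at 1.09 times control, stays open as well, as does a wrong label with no partner in the series, because gene totals do not separate transgene from endogenous reads.

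VCAN was higher in all 3 lines, in the order of their mean SEPT9 levels. GC content and length are argued against, since VCAN was called in all 3 lines after the correction, with a smallest log2 difference of 2.69. Fibroblasts among the cells are argued against: 13 fibroblast genes under 10 in control summed to a change of −0.413 normalised counts in SEPT9_v2, where VCAN rose by 678, and 3 others stood at 1020 (COL1A1), 113 (COL3A1) and 61.5 (FBN1) against 866, 148 and 78.7 in control. A first test on the list's median was dropped after it was seen, as most members lay near 0. SEPT9 dosage stays open as a hypothesis: within lines the GC- and length-corrected values of the 9 libraries gave a Pearson r of 0.63 and a Spearman rho of 0.617 (exact one-sided permutation p = 0.0556 and 0.0787, two-sided 0.167 and 0.19, r = 0.55 without the 2 libraries farthest out). In uncorrected values no line had its replicates in the same order for VCAN and SEPT9. Replicate B was highest for both in SEPT9_v1 and lowest for both in SEPT9_v3. In SEPT9_v2 the orders were opposite, with VCAN at 748, 607 and 703 where SEPT9 stood at 62009, 95778 and 67981 in A, B and C. Among the 134 genes that differed 7 followed the rising SEPT9 order and 2 the falling one, against 5.58 per order if all 24 orders were equal. Over all 16597 tested genes 1300 followed the rising order, a larger share, so the 7 do not speak for dosage.

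Other splits of the libraries. With 6 libraries there are 10 splits, too few for a share under 0.05. The real split gave the most genes against control for SEPT9_v1 (7 genes, 0 in the highest other, 1 of 10 as large), SEPT9_v2 (17 and 0, 1 of 10) and SEPT9_v3 (72 and 0, 1 of 10). It did so as well for SEPT9_v1 against SEPT9_v2 (91 and 0, 1 of 10) and SEPT9_v1 against SEPT9_v3 (28 and 0, 1 of 10). For SEPT9_v3 against SEPT9_v2, 2 of 10 splits gave as many. The other, with SEPT9_v2 A, SEPT9_v3 A and SEPT9_v3 B on 1 side, called 3845 genes against 93, which points to a structure of the samples. Its sides lay apart on the first principal component, which went with GC content, at scores of −23.53 to 1.29 against 28.74 to 64.74. For lists, 5, 3 and 2 of 10 splits called as many in SEPT9_v1, SEPT9_v2 and SEPT9_v3 against control (10, 9 and 12 lists, highest others 15, 12 and 12). In SEPT9_v1 against SEPT9_v2, SEPT9_v1 against SEPT9_v3 and SEPT9_v3 against SEPT9_v2 they were 9, 5 and 5 of 10 (6, 10 and 8 lists, highest others 14, 17 and 15). Of 100 drawn splits of the 12 libraries, 3 gave at least the 134 genes of the F test, with 3621 in the highest other. So small a share argues against chance for that count. A split that called 3621 again points to a structure of the samples, so the count alone does not separate the lines from that structure. For genes called in the same direction in all 3 comparisons with control, 1 of the 100 gave any, the real one (1 gene, 0 in the highest other). This argues against chance for the grouping of the 12 libraries, but it says little of the sharing itself. Other splits mix lines that differ, which widens their spread, and the count of 1 was 0 without control B or C.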

How the results depend on the processing

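Leaving out the 3 outlying libraries, the GC and length correction, the surrogate variable and the library weights were chosen after the data were seen; the other settings were planned. No alternative reversed any of the 69 calls of named genes. DESeq2 and recomputed median-of-ratios scaling kept all 69, as did leaving out the 3 libraries and the library weights. No filter lost 20, eBayes without trend 14, fits of only the 2 groups 13, the replicate block 6, robust eBayes 5, a pseudocount of 0.5 and quantile normalisation 3 each, edgeR 2, and a pseudocount of 5, upper-quartile scaling, the GC and length correction and the surrogate variable 1 each. A mean of at least 50 lost 4 of the 56 still tested. With an estimated correlation 0 lists were called in each comparison. The library weights had not converged, and their counts are no estimate. The causes were not tested, except that fewer libraries or genes enter some settings by construction.

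Genes called, for SEPT9_v1, SEPT9_v2 and SEPT9_v3 against control, then SEPT9_v1 against SEPT9_v2, SEPT9_v1 against SEPT9_v3 and SEPT9_v3 against SEPT9_v2. The values in the report were 7, 17, 72, 91, 28 and 93. DESeq2 on recovered reads gave 62, 95, 332, 396, 125 and 259. GC and length correction gave 60, 61, 518, 548, 172 and 348. Without the 3 outlying libraries they were 114, 83, 542, 128, 116 and 571. With 1 surrogate variable they were 357, 58, 1093, 111, 140 and 454, and with library weights 8430, 10100, 2532, 13379, 5772 and 8393. A mean of at least 50 gave 2, 16, 47, 67, 13 and 58. Only the 2 groups compared gave 0 for SEPT9_v1 and 181 for SEPT9_v2 against control and 23 between them. No filter gave 8 for SEPT9_v2 against control and 60 for SEPT9_v1 against SEPT9_v2, quantile normalisation 28 and a pseudocount of 5 gave 26 for SEPT9_v2 against control, and edgeR 3 for SEPT9_v1 against control. For SEPT9_v1 against SEPT9_v3 a pseudocount of 0.5 gave 18 and a pseudocount of 5 gave 49. Without each library in turn the ranges were 2 to 6, 2 to 9, 25 to 69, 27 to 92, 2 to 35 and 45 to 140.

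The F test called 638 genes in place of 134 with DESeq2, 641 without the 3 libraries, 706 after the GC and length correction, 898 with the surrogate variable, 15233 with library weights and 66 to 176 without each library. For the F test a fit of only 2 groups does not apply. Genes shared by all 3 lines numbered 2 in eBayes without trend, 0 in fits of only the 2 groups, 4 with DESeq2, 4 without the 3 libraries, 3 after the GC and length correction, 4 with the surrogate variable, 680 with library weights and 0 to 1 without each library, 0 without control B or C.

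The replicate block gave 3 genes for SEPT9_v1 against control and moved no other count of calls by over 1.5 times (16, 91, 105, 31 and 93), and it kept all 55 list calls. It lost 6 of the 69 gene calls: HLA-DPA1, HLA-DQA1, CALB2, PSMB9, LCP1, and NLRX1 between SEPT9_v1 and SEPT9_v3. The letters were not taken to pair the libraries, since only 7 of 18 same-letter correlations of deviations exceeded 0.1 (range −0.393 to 0.479) and 5 of 12 libraries matched their own letter best, so the calls lost are not read as weaker effects. For letter A, though, the 3 correlations between isoform lines were 0.471, 0.399 and 0.421, and for letter B that of SEPT9_v1 and SEPT9_v2 was 0.479.

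SEPT9 was called in SEPT9_v2 against control with log2 fold changes of 1.22 in a fit of only the 2 groups, 1.24 with DESeq2, 1.03 without the 3 libraries, 1.03 after the GC and length correction, 0.802 with the surrogate variable and 1.12 with library weights. In SEPT9_v3 it was called at 0.582 after the GC and length correction and 0.592 with library weights. SEPT9_v1 against SEPT9_v2 was called at −0.917 with quantile normalisation, −1.12 with DESeq2, −0.793 after the GC and length correction and −0.946 with library weights. SEPT9_v1 against SEPT9_v3 was called at −0.418 with library weights, and SEPT9_v3 against SEPT9_v2 at −0.719 without the 3 libraries and −0.528 with library weights. Without each library the SEPT9 ranges, in the order of the comparisons above, were −0.054 to 0.284, 1.03 to 1.35, 0.313 to 0.915, −1.27 to −0.931, −0.814 to −0.212 and −0.906 to −0.304. SEPT11 in SEPT9_v1 against SEPT9_v3, not called in the report, was called at −0.512, the opposite sign, with library weights.

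Lists called without each library numbered 4 to 11, 7 to 11, 6 to 12, 4 to 8, 8 to 13 and 6 to 9 in the same order. SEPT9_v1 against control had 4 without the 3 libraries, SEPT9_v1 against SEPT9_v2 had 11 with quantile normalisation and 13 after the GC and length correction, and SEPT9_v1 against SEPT9_v3 had 16 after that correction. Of the 55 list calls the GC and length correction kept 45, a mean of at least 50 kept 49, quantile normalisation kept 48, and without the 3 libraries 33 were kept, 17 ended and 5 turned. Medians that turned without the 3 libraries were mitosis in SEPT9_v1 against control (−0.007) and, in SEPT9_v1 against SEPT9_v3, mitosis (−0.163), matrix proteases (0.111), antigen presentation (0.007) and mitochondrially encoded genes (0.014). Without SEPT9_v1 A mitosis turned in the same comparisons (−0.007 and −0.094), without SEPT9_v3 B the matrix list against control (0.001), and without SEPT9_v3 C the basal list against SEPT9_v2 (−0.078). Over all libraries left out in turn, these medians ranged from −0.007 to 0.349, −0.094 to 0.362, −0.365 to 0.001 and −0.078 to 0.413. Quantile normalisation turned the ribosomal list in SEPT9_v2 (−0.097) and SEPT9_v3 (−0.041) against control. Genes near the floor rest on few reads.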

Other observations

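No test of an explanation was added in this part, and the values below were chosen after they were seen. CD74, the class II invariant chain gene, stood at 1053 in control, 201.7 in the libraries labelled SEPT9_v1, 1868 in SEPT9_v2 and 758.3 in SEPT9_v3. Its order of levels was shared by HLA-DPA1 (72.2, 12.3, 84.9 and 37.2), HLA-DRA (163.8, 33.8, 170.9 and 85.7) and CIITA (189, 55.3, 205.5 and 91.2), but not by HLA-DQA1 (27.1, 3.43, 22.1 and 13.8), which was highest in control, nor by HLA-DRB1 (627, 594, 1357 and 945). The difference of SEPT9_v1 from SEPT9_v2 was called in limma for CD74, HLA-DPA1, HLA-DRA, CIITA, HLA-DQA1 and HLA-DRB1, with adjusted p of 0.00216, 0.00495, 0.0256, 0.0256, 0.0216 and 0.0442. The list that holds them was not called with an estimated correlation in any comparison.

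The single genes ACTG2 and TAGLN were higher in SEPT9_v3 than in SEPT9_v2 and higher in SEPT9_v1 than in SEPT9_v2. ACTG2 stood at 19.7 in control, 133 in SEPT9_v1, 14.4 in SEPT9_v2 and 130.5 in SEPT9_v3, and TAGLN at 56.7, 195.2, 43 and 416. Against control, ACTG2 in SEPT9_v3 was not called (limma adjusted p = 0.117). The lists that hold them were not called in SEPT9_v1 against SEPT9_v2. Of the mesenchymal markers, with TAGLN, 3 of 13 were higher (median −0.543, camera adjusted p = 0.0636), and 5 fell and 1 rose adjusted over the list alone. The basal markers, with ACTG2, had a camera adjusted p of 0.431.

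Of the other lists fixed at the start, 12 were called in no comparison besides the septins, and the smallest camera adjusted p over the 6 comparisons was 0.0734 for focal adhesion, 0.297 for epithelial junctions, 0.169 for angiogenic factors, 0.175 for NF-kB and inflammatory genes, 0.633 for AP-1 and immediate early genes, 0.0941 for tubulins, 0.135 for Wnt and Notch, 0.545 for apoptosis, 0.439 for drug efflux and xenobiotic metabolism, 0.142 for leukocyte markers, 0.247 for endothelial markers and 0.56 for replication-dependent histones. Fibroblast markers had 3 tested members, too few for the list test.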
